A study of Drosophila melanogaster with 6 samples.

How the data were processed

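Gene expression was measured by RNA sequencing of total RNA from midguts of adult Drosophila melanogaster, in 3 libraries from flies with Rab11 RNA interference under Myo1A-Gal4 and 3 libraries from wild-type controls. The labels name both Illumina and Ion Torrent protocols and do not say which library was made with which, so the platform could not enter any fit. Groups and replicate numbers were taken from the sample titles. Nothing in the labels says whether the 3 libraries of a group came from separate pools of flies, so p-values measure the spread between these samples, which may be in part technical. Libraries of the same group differed far beyond sampling noise, with a chi-square per gene between 71.5 and 401, and no pair was treated as a repeat.

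The authors deposited a table of raw read counts per gene. Per the submitters' processing notes the tools were STAR 2.4.2a, HTSeq 0.6.1 and DESeq2, and the genome build was BDGP5; the annotation, the counting mode and the strand setting are not given in the sources used here. Where strand was not used, reads of overlapping and antisense genes cannot be told apart, and reads of near-identical copies (trypsins, Jon proteases, lysozymes, Drosomycin-like peptides) are uncertain. The authors also deposited a comparison table whose columns are, per the file headers, the DESeq2 mean normalized count and Wald statistic (scores without a fixed range), the log2 fold change with its standard error, and the p-value and adjusted p-value of each gene. All of its adjusted p lie under 0.1. Mean normalized counts in the authors' deposited table equal those of DESeq2 size factors on the count table within a relative difference of 5e-15. The count table has 15391 rows, named by gene symbols of an older annotation; 1579 rows carry an FBgn identifier in place of a symbol, and 5 rows carry names that a spreadsheet had turned into dates. A current name was found for 15156 rows. The annotation at hand is of another build (BDGP6), so it served for names and exonic lengths, and no coordinates are given. Of 1057 members of 42 gene lists fixed before the data were examined, 1054 were matched to a row.

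Depth was 9818914 to 33082790 counts per library, with the replicate 3 libraries at 33082790 in the knockdown and 30610335 in the wild type. Genes were kept by filterByExpr with a minimum count of 10, which left 8377, and library sizes were scaled by TMM (factors of 1.19, 0.90 and 1.45 in the knockdown and 0.78, 0.79 and 1.04 in the wild type). Changes between groups were tested with edgeR's quasi-likelihood F-test (edgeR 4.0.16, R 4.3.3), group as the sole term, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Standard errors were taken from the log2 fold change and its F statistic. Gene lists were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, with adjustment over the 40 lists that had at least 5 tested members; the ovary and male lists had too few. Principal components were computed on log2 CPM with a prior count of 2.

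The replicate numbers are shared between the groups. Deviations of same-numbered libraries from their group means correlated at 0.14, 0.21 and 0.71 across genes, so that the numbers were taken to pair the libraries by a rule of all 3 above 0.1, and the fit with the replicate number as a block is given where it changes a result's call or moves a count of calls by over 1.5 times. This pairing comes from the data: knockdown replicate 1 correlated more with wild-type replicate 2 (0.34), and knockdown replicate 2 with wild-type replicate 1 (0.51).

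A rule made before the data were examined set which genes could be named. It took Rab11, the 12 rising and the 12 falling genes with the largest log2 fold change among those past the threshold with a mean of at least 10 CPM and groups that do not overlap, up to 4 members of each list past the threshold in order of p, and all counted members of the lists of growth signals and JAK-STAT genes. The rule also allows the most abundant member of a list that did not pass. Not every gene it allows is named. Each list with called members is represented from its smallest p on, by at least its first 2 where it has as many, and how many followed was decided after their values were seen, in part by whether their calls held with single libraries left out. The level of alphaTry, in a list that was called, was added after its values were seen, as were the genes among the other observations.

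The test was tried on simulated counts with the means, dispersions and depths of these libraries, some of whose genes were changed by known folds, for the comparison of knockdown with wild type. Among 8281 genes tested, it recovered 0% of 48 genes changed by 1.5-fold, 2% of 50 changed by 2-fold, 61.2% of 49 changed by 4-fold and 86% of 50 changed by 8-fold, and called 2 unchanged genes. Few genes were changed there, which makes the adjusted threshold stricter than where many genes change. In these data 1397 genes passed in the fit with group as the sole term, of which 1073 changed by at least 2-fold. Calls under 2-fold thus occurred, and the recovered shares hold for the simulated setting only. Moderate changes can still be missed with 3 libraries per group and this spread. The fit with the replicate block was not tried on simulated counts. With 1 list raised by 1.5-fold in simulation, camera called it (adjusted p = 1.05e-05) and 1 of 39 others. Genes were drawn independently there, without correlation between genes and without the differences of the replicate 3 libraries. The simulation therefore cannot show how often camera calls unmoved lists in these data.

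Alternatives set before the data were examined were DESeq2 size factors, upper-quartile factors or library sizes alone in edgeR, scaling without the 20 most abundant genes, DESeq2 1.42.0, limma-voom, no filter or a minimum of 10 CPM in 3 libraries, the replicate block, robust dispersions, other thresholds, and each library left out in turn. For the lists they were an estimated correlation, fry, and camera on ranks. Added after seeing the data were fits without both replicate 3 libraries and with the depth class (replicate 3 against the other libraries) as a covariate, for the lists also library sizes alone and scaling without the 20 most abundant genes, and for the shared calls DESeq2 at an adjusted p under 0.1.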

Results

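RNA sequencing was used to measure gene expression in midguts dissected from adult Drosophila melanogaster. In the knockdown flies, an RNA interference construct against Rab11 was expressed under Myo1A-Gal4, a driver active in enterocytes, the absorptive cells that make up most of the midgut epithelium. Rab11 is a small GTPase of recycling endosomes. The control flies were described as wild type. All flies were shifted to 29 °C at 5 days after eclosion and kept there for 5 days before dissection. The 6 libraries fall into 3 from the knockdown and 3 from the wild type, and the comparison asks which transcripts of the gut change when Rab11 is depleted in its enterocytes. The knockdown libraries held 11857507, 9818914 and 33082790 counted reads for replicates 1, 2 and 3, and the wild-type libraries held 10109091, 9906918 and 30610335. The replicate 3 library of each group was thus deeper than the other 4. Values below are CPM, read counts relative to the library total, scaled by TMM and given as mean ± SD with n = 3 per group. Changes are log2 fold changes of knockdown over wild type from edgeR's quasi-likelihood test, with Benjamini-Hochberg adjusted p.

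Rab11 itself was lower in every knockdown library than in every wild-type library. Its level was 73.8 ± 8.11 CPM in the knockdown (n = 3) and 269 ± 49.8 CPM in the wild type (n = 3), so that 27.4% of the wild-type level was left. The individual libraries gave 64.4, 78.2 and 78.7 CPM in the knockdown and 319, 270 and 219 CPM in the wild type. The log2 fold change was -1.87 with a standard error of 0.23 (edgeR, adjusted p = 0.00342). An exact two-sided permutation test of the same values gave p = 0.1, the smallest p that 3 libraries against 3 allow. The RNA came from whole midguts, which also hold cells in which the driver is not active.

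The knockdown and wild-type libraries were set apart on the first principal component of log2 CPM, which held 49.4% of the variance. The second component held 30.9% and set both replicate 3 libraries apart from the other 4, in knockdown and wild type alike. The 20 most abundant genes took 16.1%, 17.1% and 10.1% of the counts in the knockdown libraries and 26.0%, 28.1% and 23.8% in the wild-type libraries. Of these 20 genes, 8 are digestive serine proteases.

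**Figure D1:**
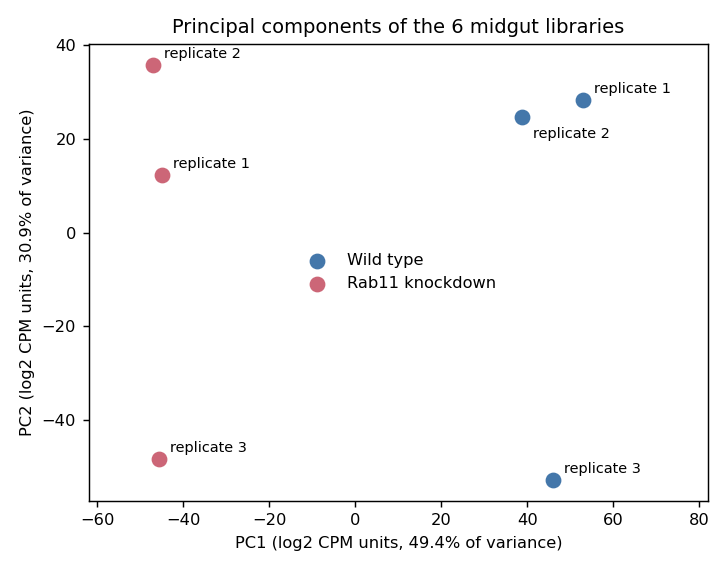
Principal components of log2 CPM over the 8377 genes tested, with the first component (49.4% of the variance) on the x axis and the second (30.9%) on the y axis, in log2 CPM units. Each point is a library. The wild-type and knockdown libraries lie at opposite ends of the x axis, and both replicate 3 libraries lie apart from the other 4 on the y axis.

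Depletion of Rab11 came with a large rise in a cytokine, in the growth factor Pvf1 and in several DNA replication genes. It also came with a large fall in several secreted digestive enzymes. The cytokine upd3, a ligand of the JAK-STAT pathway, rose from 0.836 ± 0.406 to 36.2 ± 10.1 CPM (n = 3 each), with a fitted fold change of 47.8. The protease Jon25Biii, among the most abundant transcripts of the wild-type gut, fell from 15532 ± 3689 to 552 ± 330.0 CPM, with a fitted fold decrease of 28.2. In total 1397 of 8377 genes changed at an adjusted p under 0.05, of which 758 were higher and 639 lower in the knockdown. With the replicate number as a block, 2451 genes changed, 1276 higher and 1175 lower, and 1395 of the 1397 were among them. The split between higher and lower genes depends on the scaling. With library sizes alone, the median of all genes moved up by 0.47 on the log2 scale and 82.8% of 1394 calls were higher, against 54.3% with TMM. Upper-quartile factors moved the median of all genes to 0.11. The knockdown and wild-type ranges did not overlap for 3179 genes (37.9%), where chance gives 10%.

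The count of changed genes fell when a single library was left out. It was 460, 643 and 1138 without knockdown replicates 1, 2 and 3. Without wild-type replicates 1, 2 and 3 it was 570, 759 and 1092. Each such fit holds fewer libraries and leaves the replicate 3 libraries unevenly weighted between the groups. A call lost there can thus reflect lower power, and does not by itself show that the change rests on that library. A core of 402 genes, 223 higher and 179 lower, passed whichever library was left out. The genes named below as having risen or fallen belong to it unless a loss of the call is stated. Counts of the called members of a list include genes outside it, and the number that passed with each library left out is given where not every called member is named. Without both replicate 3 libraries 1739 genes changed, 821 higher and 918 lower, of which 1193 were shared with the full set.

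The rises were ranked among genes with a mean of at least 10 CPM and groups that do not overlap. The largest were led by CG4250, at a log2 fold change of 6.64 ± 0.27 (SE, adjusted p = 0.000185), and CG7017, at 6.62. After upd3, at 5.58, came CG16959 at 5.49, CG7910 at 5.19 and Pen, a nuclear import factor of the importin alpha family, at 4.97. The protease rho, which releases ligands of the epidermal growth factor receptor, rose by 4.87 on the log2 scale, the cytoplasmic actin Act42A by 4.81, the DNA polymerase clamp mus209 by 4.76 and CG13117 by 4.70. Act42A went from 82.9 ± 73.6 to 2318 ± 680.3 CPM. The antimicrobial peptide gene Dpt rose by 4.53 and CG6933 by 4.33. Dpt varied widely between libraries, at 1.14 ± 1.54 CPM in the wild type and 22.8 ± 25.7 CPM in the knockdown. Its adjusted p of 0.048 became 0.0506 with the replicate block, and its call was lost without each library other than wild-type replicate 2 (adjusted p 0.0589 to 0.139).

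The falls were ranked among genes with the same minimum of 10 CPM and groups that do not overlap. The largest were those of CG4830, at a log2 fold change of -7.15 ± 0.79 (SE, adjusted p = 0.00293), CG12057 at -6.35, lectin-24A at -6.15 and CG34215 at -5.69. Diedel3 fell from 798 ± 343 to 25.7 ± 2.32 CPM, the proteases Jon25Biii and Jon25Bii fell by 4.82 and 4.70 on the log2 scale, and LpR1, a lipophorin receptor that takes up lipid particles, fell by 4.64. CG15263, CG30272, CG9825 and Gal, a beta-galactosidase, also fell, at log2 fold changes of -5.59, -5.51, -5.08 and -5.02. These 4 did not keep their calls. That of CG15263 was lost without knockdown replicate 1 (0.06) or knockdown replicate 2 (0.0634), and that of CG30272 without knockdown replicate 1 (0.0835) or knockdown replicate 2 (0.0585). CG9825 lost its call without each library other than wild-type replicate 1 (adjusted p 0.0632 to 0.155), and Gal without knockdown replicate 1 (0.0798), knockdown replicate 2 (0.0652) or wild-type replicate 1 (0.0537).

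**Figure D2:**
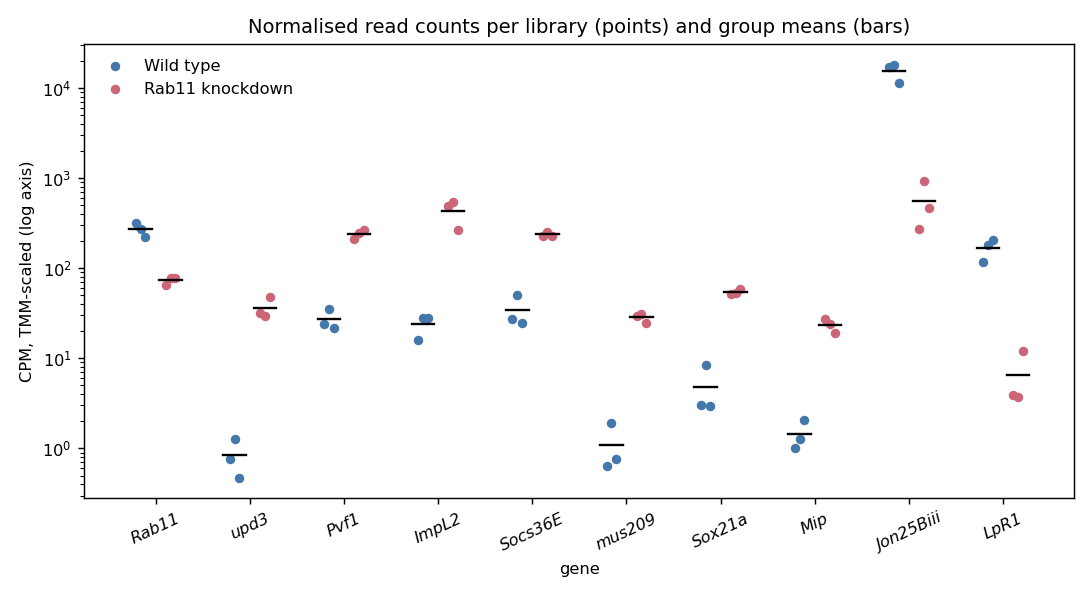
TMM-scaled CPM on a log axis for 10 genes, with a point per library and a bar at the mean of the 3 libraries of each group. Rab11, Jon25Biii and LpR1 lie lower in every knockdown library than in every wild-type library, and the other 7 genes lie higher.

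Gene lists fixed before the data were examined were tested as sets with camera at a preset inter-gene correlation of 0.01. Camera compares the members of a list with the other genes, so a call as higher or lower is relative to those. Of 40 lists with at least 5 tested members, 21 were called, 11 as higher and 10 as lower in the knockdown. With an estimated correlation camera called 0 of the 40 (9 at an unadjusted p under 0.05), while fry called 18. Other groupings of the same 6 libraries also gave list calls, up to 28 of the 40. For single genes, edgeR called 0 genes at an adjusted p under 0.05 in the 9 other groupings. At an unadjusted p under 0.05 they gave 22 to 753 genes, against 2703 in the real grouping. Each of the 9 mixes knockdown and wild type on both sides, so a real group difference adds to its spread. For lists that were not called, the range of the median over the fits without a single library is given with the library at each end. Library sizes alone move the medians of lists up with that of all genes, and this is stated where it turns a sign.

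**Figure D3:**
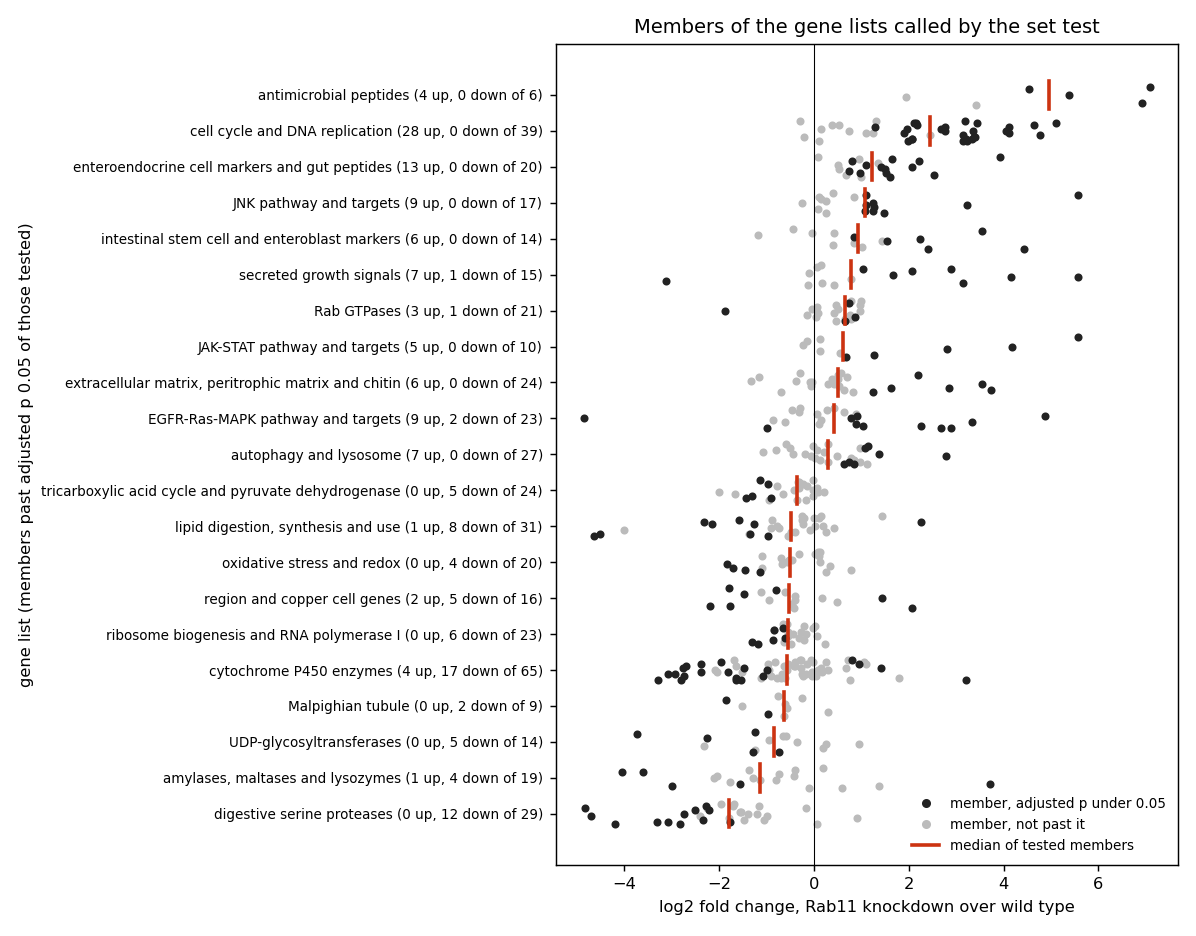
Log2 fold changes (x axis, knockdown over wild type) of the tested members of the 21 lists called by camera at the preset correlation (y axis, ordered by median). Dark points are members with an adjusted p under 0.05, grey points the others, and the red bars are the medians, which run from -1.79 for digestive serine proteases to 4.95 for antimicrobial peptides.

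Genes of the cell cycle and DNA replication rose together. Of 39 tested, 28 rose and none fell (32 rose when adjusted over the list alone), and 15 passed with each library left out. Their median log2 fold change was 2.44, with an adjusted p of 1.08e-23 in the set test (adjusted p = 0.136 with an estimated correlation). The sliding clamp mus209 rose from 1.10 ± 0.704 to 28.4 ± 3.26 CPM. The replicative helicase subunits Mcm7, Mcm5 and dpa rose by 4.04, 4.65 and 2.08 on the log2 scale.

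Of 14 markers of intestinal stem cells and enteroblasts, 6 rose and none fell (9 rose and 1 fell adjusted over the list alone, median 0.93, adjusted p = 0.00035, adjusted p = 0.426 with an estimated correlation), and with the replicate block 8 rose and 1 fell. The Notch ligand Dl, carried by stem cells, rose from 2.66 ± 0.671 to 13.9 ± 1.26 CPM, and the transcription factor Sox21a from 4.79 ± 3.13 to 54.3 ± 3.20 CPM. These were the 2 members that passed with each library left out. Of the next members by p, sna had 117 counts in the knockdown and 3 in the wild type, a ratio of 26.2 with a 95% exact binomial interval of 8.75 to 129 that covers counting error only, and Sox100B rose by 2.24 on the log2 scale. Without knockdown replicate 1 or 3, sna had too few counts to be tested, and the call of Sox100B was lost without knockdown replicate 1 (0.067), knockdown replicate 2 (0.0645) or wild-type replicate 1 (0.0802).

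Enteroendocrine markers and gut peptides rose in 13 of 20 cases and fell in none (15 rose adjusted over the list alone, median 1.23, adjusted p = 1.44e-09, adjusted p = 0.136 with an estimated correlation), and 5 passed with each library left out. The peptide genes Mip, CCHa1 and Ast-C rose by 3.92, 2.54 and 2.22 on the log2 scale, and CG13565, which encodes Orcokinin, by 1.65. Mip went from 1.45 ± 0.553 to 23.4 ± 4.04 CPM.

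Of 15 genes in the list of secreted growth signals, which also holds the receptor Pvr, 7 rose and 1 fell and 4 passed with each library left out (the same counts adjusted over the list alone, median 0.79, or 1.59 with a minimum of 10 CPM, adjusted p = 9.68e-06, adjusted p = 0.136 with an estimated correlation). The cytokine upd3, described above, is among those that rose. Pvf1, a ligand of the PDGF and VEGF receptor family, rose from 27.0 ± 7.04 to 239 ± 26.4 CPM. ImpL2, a secreted binding protein of insulin-like peptides, rose from 23.9 ± 6.98 to 428 ± 142 CPM. The ligand hh rose by 2.07, the EGF receptor ligand vn by 2.89, Pvf2 by 1.67 and Krn by 1.04 on the log2 scale, while daw, an activin-like ligand, fell by 3.12. The call of vn was lost without knockdown replicate 1 (0.0668), knockdown replicate 2 (0.057) or wild-type replicate 2 (0.0607), that of Pvf2 without any single library (adjusted p 0.0575 to 0.132), that of Krn without any single library (adjusted p 0.0674 to 0.133) and that of daw without each library other than knockdown replicate 3 (adjusted p 0.0602 to 0.166). The ligand gbb stood at 0.79 (adjusted p = 0.157, and 0.0146 with the replicate block). The other counted members, spi, wg, egr and Pvr at 0.42, 0.18, 0.15 and 0.07 and dpp and Ilp3 at -0.10 and -0.12, passed neither with nor without the block.

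Of 10 JAK-STAT genes, 5 rose and none fell (5 adjusted over the list alone, median 0.62, or 0.99 without knockdown replicate 2, 1.04 with DESeq2 and 1.08 with no filter, adjusted p = 0.000229, adjusted p = 0.136 with an estimated correlation), and 3 passed with each library left out. Besides upd3, they included the feedback inhibitor Socs36E, which rose from 34.2 ± 14.3 to 237 ± 14.9 CPM, and the stress peptide TotC, at a log2 fold change of 4.18. The phosphatase Ptp61F and TepII, a thioester protein, rose by 0.68 and 1.27. The call of Ptp61F was lost without any single library (adjusted p 0.0596 to 0.119), and that of TepII without knockdown replicate 1 (0.116), knockdown replicate 2 (0.0981), wild-type replicate 1 (0.0808) or wild-type replicate 3 (0.0765). The receptor dome was at 0.55 (adjusted p = 0.157), the kinase hop at -0.22, the transcription factor Stat92E at -0.15, chinmo at 0.14 and vir-1 at 0.12, and none of these 5 passed in edgeR with or without the block.

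In the JNK pathway, 9 of 17 genes rose and none fell (10 adjusted over the list alone, median 1.08, adjusted p = 9.68e-06, adjusted p = 0.136 with an estimated correlation), and 3 passed with each library left out. The list shares upd3, at 5.58, with the growth signal and JAK-STAT lists, so the calls of these lists are not separate. The transcription factor Ets21C rose by 3.23 on the log2 scale and the feedback phosphatase puc by 1.25, from 88.3 ± 3.55 to 209 ± 25.1 CPM. The Fos transcription factor kay rose by 1.11, a call lost without knockdown replicate 1 (0.0576) or wild-type replicate 1 (0.0634).

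In the EGFR and MAPK list, 9 of 23 rose and 2 fell (9 and 3 adjusted over the list alone, median 0.42, or 0.23 without knockdown replicate 3, adjusted p = 0.0442, adjusted p = 0.467 with an estimated correlation), and 4 passed with each library left out. The gene edl, whose protein lacks the DNA-binding domain of ETS factors, rose by 2.25, rho by 4.87 and the S-phase cyclin CycE by 2.69 on the log2 scale. The feedback inhibitor kek1 fell from 18.6 ± 9.32 to 0.639 ± 0.247 CPM. The set call ended with the replicate block (adjusted p = 0.0527), without both replicate 3 libraries (0.145), and without knockdown replicate 3 (0.181), wild-type replicate 1 (0.0581) or wild-type replicate 3 (0.0597). It also ended with library sizes alone (0.0708) and with ranks (0.0932). The Hippo and Yorkie list was not called, with CycE and vn higher and dm, which encodes Myc, lower among 20 genes (2 and 1 adjusted over the list alone, median 0.17, range 0.10 without knockdown replicate 3 to 0.27 without knockdown replicate 1, adjusted p = 0.447). With the block 5 rose and 2 fell. The call of vn was lost without knockdown replicate 1 (0.0668), knockdown replicate 2 (0.057) or wild-type replicate 2 (0.0607), and that of dm without knockdown replicate 1 (0.0785), knockdown replicate 2 (0.0521) or wild-type replicate 1 (0.0547).

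Of 20 antimicrobial peptide genes matched, 6 had enough counts to be tested, of which 4 rose and none fell (6 adjusted over the list alone, adjusted p = 3.57e-05, adjusted p = 0.221 with an estimated correlation), and 3 passed with each library left out. The median log2 fold change was 4.95, or 4.87 with the genes of 3 or fewer wild-type counts at the near end of their counting interval. It depends on which members are tested and on single libraries, at 3.45 with no filter on low counts, 3.38 with DESeq2 and 3.25 without both replicate 3 libraries. It was 3.79 without knockdown replicate 3, and 4.12, 5.57 and 4.33 without wild-type replicates 1, 2 and 3. The gene dro3 had 401 counts over the knockdown libraries and 2 over the wild-type libraries, a ratio of 135 with a 95% exact binomial interval of 37.0 to 1116 after scaling. DptB had 581 and 2 counts, a ratio of 195 with an interval of 53.8 to 1615, and dro2 rose from 0.317 ± 0.111 to 11.8 ± 8.56 CPM. These intervals cover counting error only, and dro2 and dro3 belong to a family of close copies, so that their reads are uncertain. The remaining call was that of Dpt, with an adjusted p of 0.048, or 0.0506 with the block, lost without each library other than wild-type replicate 2 (adjusted p 0.0589 to 0.139).

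Upstream of these peptides, the peptidoglycan recognition and Imd list was not called. Of 19 genes, 2 rose and 1 fell (2 and 1 adjusted over the list alone, adjusted p = 0.918), and 3 rose and 3 fell with the block. The sign of the median is not settled (median -0.04, range -0.14 without wild-type replicate 3 to 0.17 without wild-type replicate 2), and it turns positive with upper-quartile factors (0.04), library sizes alone (0.45), limma-voom (0.09), a minimum of 10 CPM (0.05) or the block (0.13). PGRP-SC1b, one of a pair of near-copies, fell by 4.28, while key, a subunit of the IKK complex, and the recognition protein PGRP-SD rose by 1.02 and 2.54. The call of PGRP-SC1b was lost without knockdown replicate 2 (0.061) or wild-type replicate 2 (0.0608), that of key without knockdown replicate 1 (0.0502), knockdown replicate 2 (0.0538), wild-type replicate 1 (0.083) or wild-type replicate 2 (0.0795) and that of PGRP-SD without any single library (adjusted p 0.0607 to 0.114).

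Of 29 digestive serine proteases, 12 fell and none rose (18 fell adjusted over the list alone), with a median log2 fold change of -1.79 and an adjusted p of 2.85e-13 (adjusted p = 0.268 with an estimated correlation). With the replicate block 21 of them fell, and 4 passed with each library left out. These were Jon25Biii, Jon25Bii, Jon25Bi, which fell from 2970 ± 422 to 164 ± 48.5 CPM, and Jon99Fi, which fell from 1501 ± 333 to 179.7 ± 86.6 CPM. The trypsin alphaTry, the most abundant member, stood at 31594 ± 12550 CPM in the wild type and 10958 ± 7627 CPM in the knockdown, with an adjusted p of 0.206, or 0.0268 with the block. Reads of alphaTry and of paired Jon genes are uncertain, because each has near-identical copies. The 20 most abundant genes, to which 8 of these proteases belong, took 10.1% to 17.1% of knockdown counts and 23.8% to 28.1% of wild-type counts.

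Among amylases, maltases and lysozymes, 4 of 19 fell and 1 rose (5 and 1 adjusted over the list alone, median -1.14, adjusted p = 0.0292, adjusted p = 0.635 with an estimated correlation), 7 fell with the block and 2 passed with each library left out. The median was -0.75 without knockdown replicate 1 and -0.37 without wild-type replicate 1. The maltase Mal-A8 fell from 1929 ± 745 to 242 ± 50.2 CPM, while the lysozyme LysX, one of a family of close copies, rose from 39.8 ± 22.1 to 524 ± 127 CPM. The maltase Mal-A7 fell by 4.04 on the log2 scale, a call lost without knockdown replicate 1 (0.0534). As a set the list lost its call without knockdown replicate 1 (adjusted p = 0.0689), knockdown replicate 3 (0.0981), wild-type replicate 1 (0.127) or wild-type replicate 2 (0.0636), and with fry (0.23) or a minimum of 10 CPM (0.0663).

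Of 31 genes of lipid digestion and use, 8 fell and 1 rose (11 and 1 adjusted over the list alone, median -0.47, adjusted p = 0.000544, adjusted p = 0.136 with an estimated correlation), and with the block 11 fell and 2 rose. LpR1 fell from 168 ± 46.7 to 6.53 ± 4.72 CPM. The acyl-CoA synthetase bgm, the carnitine palmitoyltransferase whd, which brings fatty acids into mitochondria, and the lipid droplet protein Lsd-1 fell by 2.31, 2.15 and 1.57 on the log2 scale. These 4 were the members that passed with each library left out.

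Among cytochrome P450 enzymes, 17 of 65 fell and 4 rose (21 and 5 adjusted over the list alone, median -0.57, adjusted p = 0.000225, adjusted p = 0.136 with an estimated correlation), 20 fell and 9 rose with the block, and 8 passed with each library left out. Cyp4ac1 fell from 61.2 ± 7.49 to 8.81 ± 0.243 CPM, and Cyp4d8 and Cyp6t1 fell by 3.08 and 2.38 on the log2 scale, while Cyp305a1 rose by 3.21. Of 14 UDP-glycosyltransferases, 5 fell and none rose (8 adjusted over the list alone, median -0.84, adjusted p = 0.000544, adjusted p = 0.295 with an estimated correlation), and 1 passed with each library left out. Ugt37b1 fell by 3.73 and Ugt86Dg by 2.26. The call of Ugt86Dg was lost without each library other than wild-type replicate 1 (adjusted p 0.0597 to 0.118). Markers of the Malpighian tubule were also lower as a set (below). Whether tubule tissue in the samples bears on these enzyme lists was not tested.

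Glutathione transferases were not called, with 3 of 18 higher and 1 lower (4 and 2 adjusted over the list alone, adjusted p = 0.684), 2 fell with the block and 1 passed with each library left out. Their median was -0.15 (range -0.25 without wild-type replicate 3 to 0.08 without wild-type replicate 1), positive with library sizes alone (0.30), DESeq2 (0.20) and no filter on low counts (0.21), and their mean was 0.28, the direction of the set test. GstD2 rose by 3.43 on the log2 scale and GstS1 fell by 1.27, a call lost without knockdown replicate 1 (0.0621).

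Of 20 redox genes, 4 fell and none rose (5 adjusted over the list alone, median -0.49, or -0.31 without knockdown replicate 3 and -0.25 without wild-type replicate 1, adjusted p = 0.0227, adjusted p = 0.467 with an estimated correlation), and 2 passed with each library left out. Gclc, the catalytic subunit of the enzyme that limits glutathione synthesis, fell from 569 ± 113 to 159.6 ± 8.36 CPM, and the extracellular superoxide dismutase Sod3 fell by 1.46 on the log2 scale. Without knockdown replicate 3 the set call ended (adjusted p = 0.134), as it did without both replicate 3 libraries (0.0665) and with fry (0.0502). Markers of the Malpighian tubule, an organ attached to the gut that is rich in detoxification enzymes, were lower as a set. Of 9 tested, 2 fell and none rose (2 adjusted over the list alone, median -0.62, or -0.96 without knockdown replicate 3, adjusted p = 0.0442, adjusted p = 0.635 with an estimated correlation), and none passed with each library left out. The chloride channel ClC-a fell by 1.85 and the potassium channel Ir by 0.97. The call of ClC-a was lost without knockdown replicate 1 (0.0559), and that of Ir without any single library (adjusted p 0.0528 to 0.105). The tubule set lost its call without knockdown replicate 2 (0.0916), wild-type replicate 3 (0.213) or both replicate 3 libraries (0.141), with fry (0.19), with a minimum of 10 CPM (0.0703) and with the depth class as a covariate (0.0545).

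In the tricarboxylic acid cycle list, 5 of 24 genes fell and none rose (8 adjusted over the list alone, adjusted p = 0.00496, adjusted p = 0.635 with an estimated correlation), and 8 fell with the block. The median of -0.34 turns positive with library sizes alone (0.06) and was -0.21 without knockdown replicate 3. The glutamate dehydrogenase Gdh fell by 1.31 on the log2 scale and the pyruvate dehydrogenase kinase Pdk by 1.44. Gdh lost its call without knockdown replicate 1 (0.084), knockdown replicate 2 (0.054), wild-type replicate 1 (0.0608) or wild-type replicate 2 (0.0585), and Pdk without knockdown replicate 1 (0.0841), knockdown replicate 2 (0.0553), wild-type replicate 1 (0.0613) or wild-type replicate 2 (0.0502). No member passed with each library left out, and the set call ended without knockdown replicate 3 (0.0834) and with fry (0.129).

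Nuclear-encoded genes of oxidative phosphorylation gave no call. None of 36 passed in edgeR, adjusted over all genes, adjusted over the list alone or with the block, 0 had an unadjusted p under 0.05, and DESeq2 and limma-voom called 0. Their median was 0.00 on the log2 scale (range -0.29 without knockdown replicate 2 to 0.20 without knockdown replicate 3), 0.07 with upper-quartile factors and 0.37 with library sizes alone (adjusted p = 0.815). The set was called as lower without knockdown replicate 2 (0.0474). Glycolysis was not called, with 3 of 26 lower and none higher (3 adjusted over the list alone, median -0.30, range -0.48 without wild-type replicate 3 to -0.15 without wild-type replicate 1, positive with library sizes alone, adjusted p = 0.0633), and none passed with each library left out. The set was called as lower with ranks (0.0261), without knockdown replicate 2 (0.00976) and without wild-type replicate 3 (0.0118). UGP and the trehalase Treh fell by 1.28 and 1.55. The call of UGP was lost without knockdown replicate 1 (0.0913), knockdown replicate 2 (0.0675) or wild-type replicate 1 (0.0566), and that of Treh without knockdown replicate 1 (0.113), knockdown replicate 2 (0.0627), wild-type replicate 1 (0.0801) or wild-type replicate 2 (0.0725).

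Of 23 genes of ribosome biogenesis, 6 fell and none rose (8 adjusted over the list alone, median -0.54, or -0.35 without wild-type replicate 3, adjusted p = 0.00482, adjusted p = 0.376 with an estimated correlation), 12 fell with the block and none passed with each library left out. They included dm, which fell from 119 ± 22.1 to 48.2 ± 11.9 CPM, and nclb, which fell by 0.85 on the log2 scale. The call of dm was lost without knockdown replicate 1 (0.0785), knockdown replicate 2 (0.0521) or wild-type replicate 1 (0.0547), and that of nclb without each library other than wild-type replicate 3 (adjusted p 0.061 to 0.111). Of 85 ribosomal protein genes none passed in edgeR, also adjusted over the list alone, with 2 at an unadjusted p under 0.05, 1 called by DESeq2 and 0 by limma-voom. Their median was -0.23 (range -0.81 without knockdown replicate 2 to 0.07 without knockdown replicate 3), positive with library sizes alone (0.13), with an adjusted p of 0.0738. With the block 1 rose, 1 fell and the set was called as lower (adjusted p = 0.0236). It was also called as lower with ranks (0.0027), library sizes alone (0.0118) or the depth class (0.0249). The same held without knockdown replicate 2 (2.95e-07) or wild-type replicate 3 (0.00621). Such a call is relative to the other genes, so that with library sizes alone it stood beside a positive median.

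The insulin and TOR list was not called, with 4 of 23 higher and 3 lower (5 and 7 adjusted over the list alone, median -0.27, range -0.55 without knockdown replicate 3 to -0.09 without knockdown replicate 2, positive with library sizes alone, adjusted p = 0.388), and 7 lower with the block. Of the members, 2 passed with each library left out. In it slif, an amino acid transporter, fell from 263 ± 21.2 to 60.1 ± 5.44 CPM, and ImpL2 rose by 4.16. The serine, one-carbon and purine list was not called either, with 1 of 22 higher and 2 lower (1 and 2 adjusted over the list alone, median -0.15, range -0.23 without wild-type replicate 3 to -0.13 without wild-type replicate 1, positive with library sizes alone, adjusted p = 0.124, or 0.0191 with fry), and 2 higher and 6 lower with the block. Enzymes of one-carbon and serine synthesis, pug and CG6287, fell by 1.76 and 1.56 on the log2 scale, and the thymidylate synthase Ts rose by 4.01, a call lost without knockdown replicate 1 (0.118), knockdown replicate 2 (0.11), knockdown replicate 3 (0.0501) or wild-type replicate 1 (0.117).

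Among 21 Rab GTPases, 3 rose and Rab11 alone fell (10 and 1 adjusted over the list alone, median 0.66, adjusted p = 0.0442, adjusted p = 0.401 with an estimated correlation), and 10 rose with the block. The 1 member that passed with each library left out was Rab11 itself, so none of the 3 rising genes did. Rab2 rose from 96.0 ± 5.70 to 175 ± 9.31 CPM, a call lost without each library other than knockdown replicate 3 (adjusted p 0.0549 to 0.0766). The set call ended without knockdown replicate 3 (0.0834), wild-type replicate 2 (0.0928), wild-type replicate 3 (0.0711) or both replicate 3 libraries (0.0902), and with a minimum of 10 CPM (0.0546). Exocyst genes and Rab11 effectors were not called, with 3 of 20 higher and none lower (3 adjusted over the list alone, median 0.29, range 0.20 without knockdown replicate 3 to 0.38 without knockdown replicate 2, adjusted p = 0.0998), 6 were higher with the block and none passed with each library left out. The set was called as higher with ranks (0.029) and without knockdown replicate 2 (0.0352). The syntaxins Syx7 and Syx13 rose by 0.91 and 1.17 on the log2 scale. The call of Syx7 was lost without knockdown replicate 1 (0.0727), wild-type replicate 1 (0.0879) or wild-type replicate 2 (0.0813), and that of Syx13 without each library other than knockdown replicate 3 (adjusted p 0.0774 to 0.137).

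Of 27 autophagy and lysosome genes, 7 rose and none fell (8 adjusted over the list alone, median 0.30, or 0.54 without knockdown replicate 2, 0.55 without wild-type replicate 3 and 0.51 with a minimum of 10 CPM, adjusted p = 0.0227, adjusted p = 0.19 with an estimated correlation), 12 rose and 2 fell with the block, and 3 passed with each library left out. The sterol carrier Npc2a rose from 49.9 ± 4.10 to 347 ± 57.8 CPM, and CG6194 and CG1599, which encode Atg4b and Vamp7, rose by 1.38 and 1.08 on the log2 scale. The autophagy set lost its call without knockdown replicate 3 (adjusted p = 0.0501), wild-type replicate 2 (0.0511), wild-type replicate 3 (0.0503) or both replicate 3 libraries (0.0755). Vacuolar ATPase subunits were not called, with 1 of 21 higher and none lower (none adjusted over the list alone, median -0.11, range -0.15 without knockdown replicate 2 to 0.02 without knockdown replicate 3, positive with library sizes alone (0.29), adjusted p = 0.684), and 1 lower with the block. Vha100-1, the higher member, rose by 0.67, a call lost without any single library (adjusted p 0.0877 to 0.142).

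Chaperones of the unfolded protein response were not called, with 2 of 22 higher and 1 lower (2 and 1 adjusted over the list alone, median 0.21, range 0.09 without wild-type replicate 3 to 0.28 without knockdown replicate 1, adjusted p = 0.684), and none passed with each library left out. Edem2 fell by 1.24 and the secreted factor Manf rose by 0.94 on the log2 scale. The call of Edem2 was lost without knockdown replicate 1 (0.087), knockdown replicate 2 (0.0613) or wild-type replicate 1 (0.0615), and that of Manf without knockdown replicate 1 (0.0595), knockdown replicate 2 (0.0564), wild-type replicate 1 (0.0929) or wild-type replicate 2 (0.0816). None of 19 heat shock genes passed in edgeR, over all genes, adjusted over the list alone or with the block (1 at an unadjusted p under 0.05, 1 called by DESeq2 and 0 by limma-voom, median 0.45, range 0.19 without wild-type replicate 2 to 0.97 without wild-type replicate 3, adjusted p = 0.178). That set was called as higher with ranks (0.0329), without both replicate 3 libraries (0.0249) and without wild-type replicate 3 (0.00884). Of 16 apoptosis genes, 4 rose and 2 fell (4 and 2 adjusted over the list alone, median 0.47, range 0.33 without knockdown replicate 3 to 0.55 without knockdown replicate 2, adjusted p = 0.124), and 1 passed with each library left out. The caspases Ice and Nc rose by 1.43 and 1.51, the latter a call lost without wild-type replicate 1 (0.0506).

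Matrix and peritrophic genes included further rises, with 6 of 24 higher and none lower (6 adjusted over the list alone, median 0.51, or 0.32 without wild-type replicate 1, adjusted p = 0.00614, adjusted p = 0.136 with an estimated correlation), and 3 passed with each library left out. The chitinase Cht4 rose from 62.3 ± 18.2 to 826 ± 175 CPM, and the matrix metalloprotease Mmp2 and Peritrophin-15b by 3.55 and 2.85 on the log2 scale. Enterocyte identity and septate junction genes were not called as a set. Of 20 tested, 5 rose and 2 fell (6 and 3 adjusted over the list alone, median 0.36, range 0.10 without knockdown replicate 3 to 0.55 without wild-type replicate 3, adjusted p = 0.124), and 1 passed with each library left out. The junction proteins Fas3 and cora rose by 1.47 and 1.37, the latter a call lost without knockdown replicate 1 (0.0559) or wild-type replicate 1 (0.0693). Of 16 genes of gut regions and copper cells, 5 fell and 2 rose (6 and 2 adjusted over the list alone, median -0.52, adjusted p = 0.0272, adjusted p = 0.215 with an estimated correlation), and 4 passed with each library left out. The transcription factors bab2, exex and vnd fell by 1.80, 1.47 and 1.77, and hh rose by 2.07. The set call ended without knockdown replicate 3 (adjusted p = 0.0789).

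Markers of other tissues that a dissected gut can carry were measured beside these groups. Visceral and body muscle was not called, with 1 of 22 genes higher and 1 lower (1 and 1 adjusted over the list alone, median -0.29, range -0.43 without wild-type replicate 1 to -0.03 without wild-type replicate 3, positive with library sizes alone (0.06) and without both replicate 3 libraries (0.06), adjusted p = 0.479), and 2 lower with the block. The muscle protein Zasp52 rose from 89.3 ± 15.4 to 319 ± 39.9 CPM, and the transcription factor Mef2 fell by 0.75 on the log2 scale, a call lost without any single library (adjusted p 0.0563 to 0.102). None of 7 fat body, 6 haemocyte and 10 neuron genes passed in edgeR, over all genes or adjusted over the list alone, with 1, 0 and 1 at an unadjusted p under 0.05 and 0 called by DESeq2 or limma-voom. Their set tests gave adjusted p of 0.918, 0.918 and 0.856, and with the block 1 fat body gene rose. None of the 3 medians has a settled sign, with 7 of 12, 6 of 14 and 10 of 16 members tested. That of the fat body was 0.73 (from -0.54 without knockdown replicate 3 to its highest value without knockdown replicate 1). That of haemocytes was -0.17 (range -0.32 without wild-type replicate 1 to 0.56 without wild-type replicate 3, mean 0.04, the direction of the set test), and positive with library sizes alone (0.24), DESeq2 (0.82) and no filter (1.31) and without both replicate 3 libraries (0.08). That of neurons was 0.18 (range -0.21 without wild-type replicate 1 to 0.24 without knockdown replicate 2), and negative with DESeq2 (-0.17) and no filter (-0.13) and without both replicate 3 libraries (-0.02). The ovary list had 1 gene with enough counts to be tested and the male list 0.

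Among stock markers, 1 of 6 fell and none rose (1 adjusted over the list alone, median 0.35, range -1.12 without knockdown replicate 3 to 2.07 without wild-type replicate 3, adjusted p = 0.918), namely ry, a xanthine dehydrogenase, at -1.46. The eye colour gene w, used as a transgene marker, stood at 146 ± 122 CPM in the wild type and 600.5 ± 33.5 CPM in the knockdown (adjusted p = 0.0816, or 0.0272 with the block).

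The authors' deposited table lists 2450 genes, 1209 with positive and 1241 with negative log2 fold changes. The authors' deposited table gives -1.83 for Rab11 and 5.10 for upd3, so that positive values there mean higher in the knockdown. An adjusted p under 0.05 is given for 2018 genes in the authors' deposited table. Of these, 1341 were also among the 1397 genes called by edgeR here, 56 were called here alone and 677 in the authors' deposited table alone. DESeq2 on the same counts called 2003 genes, 1906 of them shared with the authors' deposited table. No shared gene had the opposite sign in either comparison. The authors' deposited table was made from these libraries, so the overlap is not independent evidence.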

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

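Alternatives with both replicate 3 libraries left out, with the depth class as a covariate, the gene lists with library sizes alone or without the 20 most abundant genes, and DESeq2 at an adjusted p under 0.1 for the shared calls were chosen after seeing the data. Rab11 kept its direction and an adjusted p under 0.05 in every alternative run, with log2 fold changes from -2.07 to -1.40 (library sizes alone). The 1397 changed genes became 2451 with the replicate block, 2825 with the depth class, 2108 at an adjusted p under 0.1 and 460 to 1138 with single libraries left out, which leaves fewer libraries per group. The other settings gave 1073 to 2003 genes. With an estimated correlation 0 of 40 lists were called, against 21. At an adjusted p under 0.1 in both, 2026 calls were shared with the authors' deposited table, or 2332 with DESeq2, against 1341 at 0.05. No called list changed direction in its set test. The replicate block changed no set call other than those of the EGFR list and the ribosomal proteins. Called lists lost their call in 3 cases with a minimum of 10 CPM, 4 with fry, 5 without both replicate 3 libraries, 7 without knockdown replicate 3, 1 to 4 without another single library, and 1 each with the block, the depth class, library sizes alone and ranks. The platform alternative was not run, because no label gives the platform of a library. Low counts limit the folds of DptB, dro3 and sna, whose wild-type totals were 3 or fewer.

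Lists that were not called turned in direction under the settings below, given as adjusted p of the set test. No fit that turned had an adjusted p under 0.05. The ranges with single libraries left out cover all 6 fits, also those that kept the direction, to which every value under 0.05 belongs. Peptidoglycan recognition gave 0.973 with fry, 0.808 with a minimum of 10 CPM, 0.999 with the depth class and 0.654 to 0.955 with single libraries left out. Without both replicate 3 libraries, oxidative phosphorylation gave 0.763, vacuolar ATPase 0.996, muscle 0.616 and neurons 0.996. With library sizes alone, oxidative phosphorylation, fat body, neurons and stock markers gave 0.860 and haemocytes 0.970. With single libraries left out, oxidative phosphorylation went from 0.0474 to 0.853, glutathione transferases from 0.237 to 0.969, ribosomal proteins from 2.95e-07 to 0.877, heat shock from 0.00884 to 0.970, muscle from 0.12 to 0.846, fat body from 0.496 to 0.969, haemocytes from 0.671 to 0.97, neurons from 0.708 to 0.951 and stock markers from 0.270 to 0.998.

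Genes that did not pass also turned in sign, as log2 fold changes. With library sizes alone Ilp3 was at 0.37, Stat92E at 0.34, dpp at 0.30 and hop at 0.26. With limma-voom Ilp3 was at 0.026 and Pvr at -0.00728, and without both replicate 3 libraries Pvr was at -0.14 and dpp at 0.34. With single libraries left out the values lay between -0.50 and 0.18 for Ilp3, -0.14 and 0.19 for Pvr, -0.54 and 0.077 for Stat92E, -0.17 and 0.38 for chinmo, -0.42 and 0.38 for dpp, -0.063 and 0.30 for vir-1, and -0.0061 and 0.29 for wg. Where nothing in the construction of an alternative accounts for a difference, the cause was not tested.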

Other observations

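The lists, families and genes in the first 2 paragraphs, the tests of the rise of cell cycle, stem cell and enteroendocrine genes and the counts of genes in other groupings were chosen only after the results were seen. The 6 lists were made after the values of their members were seen. Their set test p-values are thus descriptive and give no independent support. Most of the actin cytoskeleton genes picked in this way rose in the knockdown. Of 18 actin, Arp2/3 and actin-binding genes, 15 rose and none fell (median log2 fold change 1.44, adjusted p = 1.21e-13 over the 6 lists chosen in this way, adjusted p = 0.0757 with an estimated correlation), and 9 passed with each library left out. The thymosin-like protein cib rose by 2.88 on the log2 scale, from 137 ± 43.1 to 1008 ± 65.4 CPM. The Arp2/3 subunit Arpc3A and the capping protein cpa rose by 1.65 and 2.04. Genes of endosomal sorting and the retromer, which handle cargo that has been taken up, rose in 13 of 19 cases and fell in none (median 1.17, adjusted p = 3.97e-10, adjusted p = 0.116 with an estimated correlation), and 7 passed with each library left out. The ESCRT-III subunit vps2 rose from 35.1 ± 3.90 to 154 ± 20.5 CPM, and the sorting nexins Snx3 and Snx1 rose by 1.54 and 1.39.

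Peroxisomal genes fell in 6 of 15 cases and rose in none (median -0.59, adjusted p = 8.40e-05, adjusted p = 0.0757 with an estimated correlation), and 1 passed with each library left out. They were led by the acyl-CoA oxidase Acox57D-d at -2.57. Of 8 clock genes 3 fell and none rose (median -0.67, adjusted p = 0.00343, adjusted p = 0.12 with an estimated correlation), namely per, tim and Clk at -1.01, -1.78 and -1.38. The call of per was lost without knockdown replicate 1 (0.085), knockdown replicate 2 (0.0547), wild-type replicate 1 (0.0704) or wild-type replicate 2 (0.0573), that of tim without knockdown replicate 1 (0.0788) or wild-type replicate 1 (0.0605) and that of Clk without knockdown replicate 1 (0.0748) or wild-type replicate 1 (0.0645). Of 20 proteasome genes 5 rose and none fell, and 20 rose with the replicate block (median 0.90, adjusted p = 6.85e-06, adjusted p = 0.311 with an estimated correlation), but 1 passed with each library left out. Of 71 mitochondrial ribosomal protein genes edgeR called none, with 14 at an unadjusted p under 0.05, 1 called by DESeq2, 0 by limma-voom and 8 higher with the block (median 0.41, adjusted p = 0.00225, adjusted p = 0.568 with an estimated correlation). That set lost its call without knockdown replicate 2 (0.140). A scan of 60 families of genes with a shared symbol stem, run at the preset correlation alone, called 12. Those called included the proteasome stems Rpn (adjusted p = 0.0083) and Pros (0.0141) and the mitochondrial ribosomal stem mRpL (0.0375). Not called were Act (1 of 5 rose and 1 fell, 0.524), Arp (2 of 6 rose, 0.226) and Vps (2 of 12 rose, 0.138). Nor were Pex (3 of 12 fell, 0.0633) and mRpS (0.102). The stems that overlap the actin, endosomal and peroxisomal lists thus gave no call. They are other groups of genes than the lists, without Arpc3A, cpa, cib, vps2, Snx3 and Snx1, so they do not test the lists.

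The rise of cell cycle, stem cell and enteroendocrine genes beside the fall of digestive proteases was weighed against 3 explanations. Counts freed by the 20 most abundant genes raise every other gene by 1 factor, which their shares of the counts set at 0.12 to 0.32 on the log2 scale over the 9 pairs of a knockdown and a wild-type library. With library sizes alone (1 CPM added) the medians rose by more in every pair, by at least 1.34 for the cell cycle, 0.72 for the stem cell and 0.78 for the enteroendocrine genes. The smallest difference in a pair was 0.52, which argues against such genes as the whole cause of the rise. The median of all genes, at 0.47 with library sizes alone in edgeR, also lay above that factor. Passing it is therefore not particular to these lists. In that fit their medians lay 2.36, 0.94 and 1.22 above the median of all genes. The cell cycle median was 1.93 in the replicate 3 pair (log2 ratio of CPM with 1 added) and 2.53 in the other 4 libraries (edgeR fit). Each group holds a replicate 3 library, so a shift of equal size in both could not by itself part the groups. The replicate 3 libraries' shift followed exonic length more in the knockdown (Spearman's rho 0.411) than in the wild type (0.185). An unequal part of it could enter the comparison, which was not tested. The cell cycle values show only that the rise of these genes was present in both sets of libraries. A lower share of enterocytes alone would raise the markers of every other cell type alike. The enteroendocrine median of 1.23 lay 1.52 above the muscle median of -0.29 (permutation test over 20 and 22 genes, two-sided, 100000 resamples, p = 3e-05, genes not being independent replicates). With a single library left out the difference ran from 1.08 (without wild-type replicate 3) to 1.71 (without wild-type replicate 1). It was 1.01 without both replicate 3 libraries. The comparison was set after values were seen, so its p is descriptive. The difference argues against a uniform loss of enterocytes as the whole cause, with muscle the only tissue tested. Medians of other non-enterocyte lists were mixed, at 0.73 (fat body), 0.18 (neurons), -0.17 (haemocytes) and -0.62 (Malpighian tubule). The enterocyte identity and junction list, which such a loss would lower, had a median of 0.36 (5 of 20 rose, 2 fell). The comparison with muscle cannot tell more stem or enteroendocrine cells from a change of expression within cells. Rab11 depletion itself and a difference in strain background between the groups stay open, since they cannot be separated in this design. A change in the mix of cells under either also stays open.

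Both replicate 3 libraries lay apart from the other 4 on the second principal component. After every library was thinned to 9818914 counts they were still apart, on a component that held 30.5% of the variance, which argues against depth as the cause. The log2 ratio of the replicate 3 library to the others followed exonic length across 8253 genes (98.5% of those tested), with Spearman's rho of 0.185 in the wild type and 0.411 in the knockdown. These values, across genes that are not independent replicates, leave gene length bias open. A difference of platform was not testable without labels, and no biological explanation was tested.

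Of the 10 ways to part the 6 libraries into 3 and 3, only the real one, 1 of 10, gave as many changed genes, 1397 against a highest other count of 0 (edgeR, unadjusted p under 0.05 for 2703 genes against 22 to 753). Every other split mixes knockdown and wild type on both sides, so a real group difference adds to its spread and lowers its count. For the set tests 3 of the 10 called at least as many lists, the real one with 21 and the highest other with 28. With 10 splits the share cannot fall under 0.05. The split with 28 lists set knockdown replicates 1 and 3 with wild-type replicate 2 against the rest. It parts all 3 replicate pairs, as does the real split and as do 2 others with 10 and 13 lists. Those 3 splits differ from the real one in mixing both groups, as all other splits do.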
